A study of Mus musculus with 14 samples.

How the data were processed

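Left ventricular RNA from male C57BL/6 mice, wild type or lacking Hspb8, was measured on 14 Affymetrix mouse genome arrays (Mouse430_2): 3 basal wild type, 3 basal knockout, and 4 wild type and 4 knockout after 3 days of pressure overload (TAC). Groups were read from the sample titles. RNA was extracted with Trizol and labelled with biotin, per the labels. The deposited values are log2 expression values per probe set that the authors made from the probe intensities with RMA, as the submitters' processing notes say; the RMA version, and whether all arrays were normalized together, are not given in the sources used here. The values carry 2 decimals, with no missing value and 64 control probe sets. Which part of Hspb8 was removed is not given in the sources used here. The raw intensities were not used here. Names of array files put the basal arrays in one run and the TAC arrays in another far later, and basal KO 3 on another day than the other basal arrays. The contrast between genotypes after TAC lies within a run. That between genotypes in basal hearts lies within a run but not within 1 day, because of basal KO 3, and contrasts between TAC and basal arrays cross runs.

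Probe sets took their gene symbol from the platform annotation, matched to RefSeq genes of GRCm38.p6: 34958 probe sets had 1 symbol, 932 had several and 9211 had none. Of the symbols, 34754 were matched by gene number and 1 by accession, 203 were not matched and 1 was updated. A probe set was kept if its log2 value exceeded the median of the whole table, 5.75, in at least 3 arrays, which left 24525. A fold is a lower bound where the mean of the lower group lies below that median. Each gene was represented by its kept probe set with the highest mean over all arrays, which gave 12260 genes (18193 with no filter).

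Genes were tested in R 4.3.3 with limma 3.58.1. A linear model with the 4 groups was fitted to all 14 arrays, so that each gene has 1 spread for all groups (10 residual degrees of freedom, 3.43 prior ones), followed by eBayes with a constant prior. The contrasts were TAC against basal in each genotype, knockout (KO) against wild type (WT) in each condition, and the difference of the KO effects. A gene passed with a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values in the text come from limma unless another test is named, SE is the model's standard error, and ± gives the SD between arrays. Tests of single values were exact permutation tests over arrays.

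There were 29 gene lists: hypertrophy and fetal program, adult contractile and calcium handling, chaperones, unfolded protein response, proteasome, autophagy and lysosome, nuclear genes of oxidative phosphorylation, fatty acid oxidation, TCA cycle and pyruvate dehydrogenase, glycolysis and glucose uptake, mitochondrial regulators, STAT3 and acute phase targets, matrix and fibrosis, cell cycle, immediate early genes, interferon response, circadian clock, ribosomal proteins, and markers of macrophages, neutrophils, lymphocytes, endothelium, smooth muscle and pericytes, fibroblasts, adipocytes, skeletal muscle, atrial cardiomyocytes, epicardium and erythroid cells. The 28 lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists; the erythroid list had 3. The matrix and fibroblast lists share 5 genes, the hypertrophy and atrial lists 3, and the STAT3 and immediate early lists 3. Camera tests a list against the other genes and takes genes as nearly independent at this preset; the same test with the correlation estimated from the data is given beside each call. Members were also adjusted over their list alone.

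The genes named in the text were set by rule: Hspb8 on each of its probe sets; Stat3, Nos2, Nos3, Bag3, Nppa, Nppb, Myh6 and Myh7 in every comparison; the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap (no such condition for the difference of KO effects), or all that pass if fewer; the 5 with the smallest p where none pass; and up to 4 members per list with the smallest p. The groups, comparisons, tests, lists, this rule and the first set of alternatives were fixed before the data were examined.

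The alternatives were no filter; a stricter filter (above the 75th percentile, 7.7); the mean of a gene's probe sets; every probe set on its own; quantile normalization; centring each array on its median; a fit on the arrays of the comparison alone; eBayes with a trend, and with a trend and robust; array weights; the replicate number as a block; a fold change of at least 1.5; leaving out each array in turn; and, for lists, camera with an estimated correlation and fry. Chosen after seeing the data were leaving out probe sets of the class that can bind other transcripts, the first principal component of the TAC arrays as a covariate (with either correlation for lists), exact permutation tests of list means, the average of the KO effects, and the lists after quantile normalization and median centring. Where leaving out an array leaves fewer in a group, its spread is taken to be like that of the other groups. Other splits of the arrays were counted in full (10 or 35) or, for the difference of KO effects, as 100 of 700 drawn with a fixed seed.

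The fit was tested on simulated data with 100 changed genes at each of 2 sizes among 12260. Noise was drawn independently for each gene with 1 spread for all groups. Structure shared between genes and the wider spread of TAC wild type were left out, so the shares below may be too favourable for contrasts with TAC arrays. A log2 change of 1 was recovered for 68% of genes between genotypes in basal arrays, 77% between genotypes after TAC, 81% between TAC and basal in wild type and 77% in knockout. A log2 change of 0.5 was recovered for 20%, 34%, 23% and 29%. Of 91, 115, 110 and 112 calls, 3, 4, 6 and 6 were false. The median SD of a gene between arrays was 0.150 in basal wild type, 0.135 in basal knockout, 0.207 in TAC wild type and 0.166 in TAC knockout (log2).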

Results

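Left ventricles of male C57BL/6 mice were measured on 14 arrays. The mice carried either the wild-type Hspb8 gene, which encodes the small heat shock protein Hsp22, or a knockout of it. Basal hearts gave 3 wild-type and 3 knockout arrays. Hearts after 3 days of pressure overload by transverse aortic constriction (TAC), a surgery that narrows the aorta so that the left ventricle pumps against a raised pressure, gave 4 wild-type and 4 knockout arrays. The median log2 value of an array ran from 5.7 to 5.8. Lower quartiles ran from 4.33 to 4.58 and upper quartiles from 7.57 to 7.84. The number of arrays limits the precision. Across genes, which are not independent replicates, arrays of the same group correlated with r of 0.989 to 0.990 in basal wild type, 0.990 in basal knockout, 0.967 to 0.993 in TAC wild type and 0.986 to 0.995 in TAC knockout. Nothing in the labels says that each array came from a separate animal, so the p-values measure only the spread between samples.

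Hspb8 (chromosome 5, 116408491 to 116422864 in GRCm38.p6), the gene targeted in these mice, read 10.26 or more in every wild-type array and 5.92 or less in every knockout array on 2 of its 3 probe sets. The one brighter in wild type read 11.68 ± 0.36 (log2, mean ± SD, n = 3) in basal wild type and 4.83 ± 0.38 (n = 3) in basal knockout, lower by log2 -6.84 (SE 0.30, adjusted p = 5.97e-08 over all probe sets). After TAC it read 11.52 ± 0.53 (n = 4) in wild type and 4.74 ± 0.34 (n = 4) in knockout, lower by log2 -6.78 (SE 0.26, adjusted p = 1.17e-08). The other read 5.79 ± 0.12 in basal knockout against 11.27 ± 0.38 in basal wild type, and 5.32 ± 0.15 against 10.61 ± 0.51 after TAC. These differences are lower bounds on the loss and no fold is given, because the knockout values lay below or near the filter of 5.75. The remaining probe set, of a class whose probes can bind other transcripts, differed by log2 -1.08 in basal hearts (adjusted p = 0.196) and by log2 -0.60 after TAC (adjusted p = 0.274). It has the highest mean over all arrays and stood for Hspb8 in the tests per gene, so that Hspb8 was not called there (adjusted p = 0.208 and 0.299). In wild type after TAC, the first of the pair differed by log2 -0.16 (adjusted p = 0.659), the second was lower (log2 -0.66, adjusted p = 0.0321) and so was the remaining one (log2 -0.71, adjusted p = 0.0036).

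**Figure D1:**
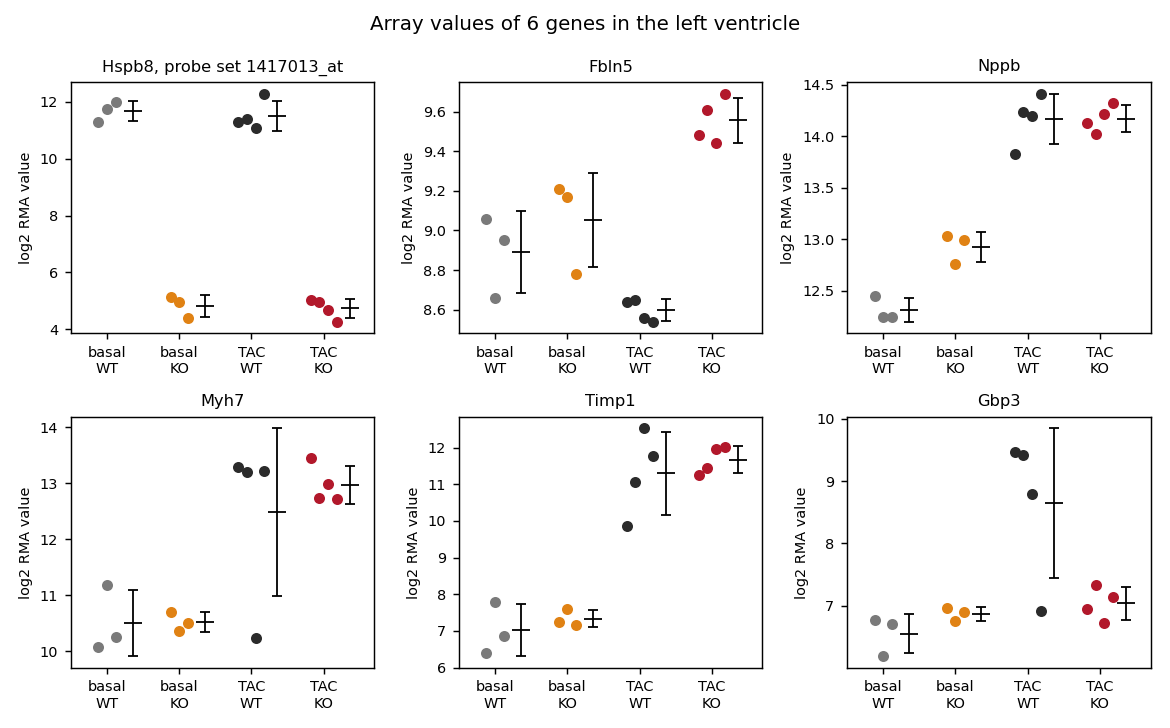
Log2 level of 6 genes in the 4 groups, with 1 point per array and bars for the mean ± SD. Hspb8 (the probe set brighter in wild type of the pair lost in knockout) lies at 4.83 and 4.74 in the knockout groups and at 11.68 and 11.52 in the wild-type groups, and Fbln5 is higher in the 4 TAC knockout arrays (9.44 to 9.69) than in the 4 TAC wild-type arrays (8.54 to 8.65).

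The first comparison sets wild-type ventricles after 3 days of TAC against basal ones. No group is labelled as sham-operated, so raised pressure cannot be told apart from the operation itself, here or in the knockout. Tnc, a matrix glycoprotein of injured tissue, was 32.6-fold higher after TAC (log2 5.03, SE 0.62, adjusted p = 0.000122, 4 against 3 arrays), and Timp1, an inhibitor of matrix metalloproteinases, was 19.4-fold higher (log2 4.28, SE 0.49, adjusted p = 8.57e-05). Sprr1a, a small proline-rich protein of stressed cells, rose 20.7-fold, the collagen-associated Cthrc1 14.6-fold, the macrophage lectin Chil3 13.9-fold, the chemokine receptor Cxcr6 13.7-fold and Col8a1 11.8-fold. Nmrk2, a kinase of NAD synthesis, rose 11.5-fold, and Gask1b, the collagen crosslinking enzyme Lox, the lipocalin Lcn2 and Cilp rose by 8.74-fold to 9.44-fold. The basal means of Sprr1a, Cthrc1, Chil3 and Cxcr6 lay below the filter value, so their folds are lower bounds. Nppb, the natriuretic peptide that is a standard marker of a loaded ventricle, rose 3.61-fold (adjusted p = 7.74e-06), and Myh7, the slow myosin heavy chain of the fetal ventricle, rose 3.94-fold (log2 1.98, adjusted p = 0.0138). Without TAC WT 3, which read 10.24, Myh7 was at log2 2.72, and its call was lost without basal WT 1 (adjusted p = 0.0535) and in a fit on the arrays of the comparison alone (adjusted p = 0.0669). Nppa (log2 0.44, adjusted p = 0.275) and the adult heavy chain Myh6 (log2 -0.06, adjusted p = 0.659) did not pass.

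Sln, the sarcolipin of atrial muscle, was lower in wild type after TAC (log2 -3.80, adjusted p = 0.0451). Its call was lost without any 1 of basal WT 1, 2 or 3, basal KO 1, TAC WT 1, 3 or 4, or TAC KO 3 (adjusted p = 0.0519 to 0.124), with array weights (log2 -2.26, adjusted p = 0.174), with the replicate block (adjusted p = 0.0912) and after median centring (adjusted p = 0.0503). The carboxylesterase Ces1d was 7.73-fold lower, the atrial myosin-binding protein Mybphl 5.88-fold, the lipid transfer protein Stard10 5.36-fold and Doc2g 5.34-fold. Cytl1, Tnxb, Dkk3, Pla2g5, Gm19277, Lgals4 and Ppargc1a, a coactivator of mitochondrial genes, were between 4.72-fold and 5.19-fold lower. In all, 6214 of 12260 genes passed an adjusted p of 0.05 in limma, 3298 higher and 2916 lower. The 3 basal and 4 TAC arrays did not overlap for 6114 genes (49.9%, against 5.71% by chance). Basal and TAC arrays were hybridized in runs far apart, so that run and surgery cannot be told apart here or in the knockout. The share of changed genes that were higher, 53.1% as deposited, was 41.3% after quantile normalization and 63.0% after centring each array on its median.

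Of the 28 gene lists tested, 8 rose and 5 fell in wild type after TAC relative to the other genes (limma camera). Matrix genes were higher for 24 of 37 members and lower for 3 (25 and 3 adjusted over the list alone; median log2 1.20, adjusted p = 5.33e-05), with Thbs4 at 5.57-fold and the periostin gene Postn at 7.50-fold. In the hypertrophy and fetal list 16 of 21 members rose and 1 fell (17 and 2 adjusted over the list alone; adjusted p = 7.72e-05), among them the stretch sensor Ankrd1 (log2 1.24) and Enah (log2 1.49). Cell cycle genes rose for 21 of 35 members and fell for 1 (25 and 1 adjusted over the list alone; adjusted p = 8.39e-05), with the helicase subunit Mcm5 at 4.94-fold and the proliferation marker Mki67 at 6.82-fold. Without TAC WT 3 the mean of this list went from log2 1.34 to 0.89. Interferon response genes rose for 16 of 18 members (17 adjusted over the list alone; median log2 1.21, adjusted p = 8.39e-05), with Oasl2 at 4.28-fold, Gbp2 at 4.07-fold and Ifit2 at 3.48-fold. Macrophage markers rose for 18 of 23 members and fell for 1 (18 and 1 adjusted over the list alone; adjusted p = 0.000273), with Cd68 at 5.17-fold. Each of these 5 lists had an adjusted p = 0.715 with an estimated correlation.

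A further 3 lists rose in wild type. Ribosomal protein genes were higher for 18 of 39 members (14 adjusted over the list alone; median log2 0.35, adjusted p = 0.00028), proteasome genes for 16 of 33 with 1 lower (16 and 1 adjusted over the list alone; adjusted p = 0.000812), and STAT3 and acute phase targets for 14 of 32 with 3 lower (14 and 3 adjusted over the list alone; adjusted p = 0.0343). Each had an adjusted p = 0.715 with an estimated correlation. The proteasome mean went from log2 0.33 to 0.17 after quantile normalization. Psma5, a subunit of the proteasome core, was 2.22-fold higher, and Fgl2 was 3.95-fold higher among the STAT3 targets. The STAT3 list lost its call without basal WT 1 (adjusted p = 0.196) or TAC WT 2 (adjusted p = 0.0615), with the mean of each gene's probe sets (adjusted p = 0.128) and after median centring (adjusted p = 0.0534).

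In the fatty acid oxidation list 17 of 29 members fell in wild type after TAC and none rose (the same counts adjusted over the list alone; median log2 -0.62, adjusted p = 8.39e-05, and adjusted p = 0.715 with an estimated correlation), among them Acads, the short-chain acyl-CoA dehydrogenase (3.16-fold lower), and Mlycd (2.31-fold lower). Of 74 nuclear genes of oxidative phosphorylation, 19 fell and 4 rose (7 and 1 adjusted over the list alone; adjusted p = 0.000273, 0.715 with an estimated correlation), with Uqcrc1 of complex III 1.96-fold lower. The list mean went from log2 -0.25 to -0.14 without TAC WT 3. Of 20 genes of the TCA cycle, 6 fell (5 adjusted over the list alone; adjusted p = 0.0285, 0.715 with an estimated correlation). That call was lost without basal WT 1 (adjusted p = 0.0536), without TAC WT 3 (adjusted p = 0.14, mean log2 -0.17 against -0.31) and with no filter (adjusted p = 0.126). Atrial cardiomyocyte markers fell for 5 of 9 members (5 adjusted over the list alone; median log2 -1.53, adjusted p = 0.0145, 0.715 with an estimated correlation), including Dbh. Lymphocyte markers fell for 3 of 6 (5 adjusted over the list alone; adjusted p = 0.0382, 0.715 with an estimated correlation), a call lost without basal WT 2 (adjusted p = 0.0767) or TAC WT 1 (adjusted p = 0.0515), with the replicate block (adjusted p = 0.0596), with the mean of probe sets (adjusted p = 0.0878) and after quantile normalization (adjusted p = 0.0795).

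The other 15 lists did not pass in wild type, though single members did. Glucose uptake and glycolysis split, with 5 of 18 members higher, among them the glucose transporter Slc2a1 (3.81-fold) and Pfkp (2.87-fold), and 7 lower (adjusted p = 0.962). Endothelial markers were lower for 10 of 20 members, among them the receptor Tie1 (2.03-fold), and higher for 1 (adjusted p = 0.0566). Fibroblast markers were higher for 6 of 18, all collagens of the list included (Col3a1 5.03-fold, Col1a1 4.49-fold), and lower for 7 (adjusted p = 0.986). Chaperones were higher for 7 of 26 and lower for 1, Fkbp4 (adjusted p = 0.215), and genes of the unfolded protein response higher for 7 of 24, such as Hsp90b1 (log2 1.18), and lower for 2, Herpud1 and Chac1 (adjusted p = 0.0944). Autophagy and lysosome genes were higher for 4 of 26, such as Lamp2 (log2 0.88), and lower for 9, such as Sqstm1 (log2 -0.72; adjusted p = 0.215 for the list). Mitochondrial regulators were higher for 3 of 22 and lower for 6 (adjusted p = 0.0572). Adult contractile genes were higher for 2 of 23 and lower for 3, with muscle creatine kinase, Ckm, 2.53-fold lower (adjusted p = 0.382). Immediate early genes had 5 of 22 members higher and 4 lower, with Klf2 3.39-fold lower (adjusted p = 0.949), circadian clock genes 3 of 16 higher and 3 lower (adjusted p = 0.577), and smooth muscle and pericyte markers 3 of 14 higher and 4 lower (adjusted p = 0.728). Skeletal muscle markers (1 of 7 higher, 4 lower, adjusted p = 0.0944), adipocyte markers (3 of 7 lower, adjusted p = 0.257), epicardial markers (3 of 9 higher, 1 lower, adjusted p = 0.833) and neutrophil markers (1 of 5 lower, adjusted p = 0.833) did not pass. Of the erythroid markers, with 3 measured members and no list test, Alas2 differed by log2 -1.17. Its call was lost in several settings, among them without TAC WT 3 (log2 -0.78, adjusted p = 0.0956), without basal WT 1 (log2 -0.88, adjusted p = 0.154) and with array weights (log2 -0.82, adjusted p = 0.0797). Adjusted over the list alone, the counts higher and lower were 1 and 1 for contractile genes, 6 and 1 for chaperones, 7 and 7 for glycolysis, 4 and 4 for smooth muscle, 7 and 8 for fibroblast and 0 and 1 for adipocyte markers, and the same as over all genes for the other 9 lists. For immediate early genes and neutrophil markers the median and mean were above 0 where camera pointed down, for fibroblast markers below 0 where it pointed up, and for glycolysis the mean alone was above 0.

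In the knockout ventricle the same surgery was followed by rises in many of the same genes. Sprr1a was 38.1-fold higher after TAC (log2 5.25, SE 1.06, adjusted p = 0.00221, 4 against 3 arrays), Tnc 37.1-fold (log2 5.21, SE 0.62, adjusted p = 0.000171) and Cthrc1 36.1-fold (log2 5.17, SE 0.72, adjusted p = 0.000348). Timp1, Lcn2, Lox, Chil3 and Cxcr6 were 20.2-fold, 16.4-fold, 16.0-fold, 15.7-fold and 14.8-fold higher. Serpinb1a, the motility protein S100a4, the replication enzyme Top2a and Adam12 rose by 9.61-fold to 12.8-fold. The folds of Cthrc1, Chil3, Cxcr6, Top2a and Adam12 are lower bounds, with basal means below the filter value. Doc2g (7.29-fold lower), Ces1d (7.01-fold lower), Kcnip2, a subunit of the cardiac transient outward potassium channel (6.05-fold lower), Tnxb, Dhrs7c and Bcat2, which starts branched-chain amino acid breakdown (5.68-fold lower), led the falls. Rpl3l, Stard10 and Fbln1 were 4.86-fold, 4.49-fold and 3.92-fold lower. Asb14 (log2 -2.22), Scara5 (log2 -2.07) and Mylk4 (log2 -2.07) passed as well. The call of Asb14 was lost without basal KO 1, 2 or 3 or TAC KO 4 (adjusted p = 0.0627 to 0.0738), that of Scara5 without basal KO 2 (adjusted p = 0.0506), and that of Mylk4 without any 1 of the 6 basal arrays or TAC KO 2, 3 or 4 (adjusted p = 0.0511 to 0.125) and with the replicate block (adjusted p = 0.0626). Nppb rose 2.37-fold (adjusted p = 9.45e-05) and Myh7 5.44-fold (adjusted p = 0.00565), while Nppa (log2 0.78, adjusted p = 0.0699) and Myh6 (log2 -0.10, adjusted p = 0.475) did not pass. In all, 5451 genes passed in limma, 2781 higher and 2670 lower, and 6662 genes did not overlap between the 3 basal and 4 TAC arrays (54.3%, against 5.71% by chance). The share that was higher, 51.0% as deposited, was 43.3% after quantile normalization and 53.9% after median centring.

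After TAC 7 lists rose and 5 fell in the knockout, each with an adjusted p = 0.643 with an estimated correlation. Ribosomal proteins rose (28 of 39 higher, 30 adjusted over the list alone; adjusted p = 6.71e-09). Matrix genes did too (27 of 37 higher and 1 lower, 29 and 2 adjusted over the list alone; median log2 1.54, adjusted p = 1.11e-08), as did cell cycle genes (25 of 35 higher, 29 adjusted over the list alone; adjusted p = 1.41e-07). Macrophage markers (19 of 23 higher, 20 adjusted over the list alone; adjusted p = 2.19e-06) and the proteasome (18 of 33 higher and 1 lower, the same adjusted over the list alone; adjusted p = 3.11e-05) rose. The last risers were hypertrophy and fetal genes (13 of 21 higher and 1 lower, 14 and 1 adjusted over the list alone; adjusted p = 5.72e-05) and STAT3 targets (18 of 32 higher and 3 lower, 19 and 3 adjusted over the list alone; adjusted p = 0.00108). Among their members Rps25 was 3.80-fold, Postn 7.11-fold, the cyclin Ccnb2 8.15-fold and the galectin Lgals3 7.28-fold higher. Oxidative phosphorylation (25 of 74 lower and 1 higher, 22 and 1 adjusted over the list alone; adjusted p = 2.58e-05) and fatty acid oxidation (17 of 29 lower, 19 adjusted over the list alone; median log2 -0.67, adjusted p = 5.91e-05) fell. So did mitochondrial regulators (11 of 22 lower and 2 higher, 12 and 3 adjusted over the list alone; adjusted p = 0.00108), the TCA cycle (8 of 20 lower, 8 adjusted over the list alone; adjusted p = 0.00354) and endothelial markers (9 of 20 lower and 1 higher, 10 and 1 adjusted over the list alone; adjusted p = 0.0058). Acads was 3.10-fold, the mitochondrial deacetylase Sirt3 2.32-fold and Tie1 2.87-fold lower.

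Interferon response genes did not pass in the knockout after TAC (median log2 0.21, adjusted p = 0.353). Of 18 members, 2 rose (2 adjusted over the list alone), Trim30a (log2 1.28) and Ifit2 (log2 0.88), the latter not without basal KO 2 (adjusted p = 0.0846). Chaperones (4 of 26 higher and 5 lower, adjusted p = 0.239) included Fkbp4 at 3.68-fold, Hsph1 at 3.37-fold and Hspa4l at 2.10-fold lower. Fibroblast markers had 7 of 18 higher and 4 lower (adjusted p = 0.353). Neutrophil markers had 2 of 5 higher, the calprotectin genes S100a8 (log2 1.88) and S100a9 (log2 1.96; adjusted p = 0.402 for the list). Lymphocyte markers had 0 of 6 changed (adjusted p = 0.27). Atrial markers had 3 of 9 lower (adjusted p = 0.13), glycolysis 5 of 18 higher and 9 lower (adjusted p = 0.402). Contractile genes had 1 of 23 higher and 6 lower (adjusted p = 0.229) and autophagy genes 4 of 26 higher and 7 lower (adjusted p = 0.311). The unfolded protein response (3 of 24 higher and 3 lower, adjusted p = 0.407), immediate early genes (3 of 22 higher and 4 lower, adjusted p = 0.974), clock genes (3 of 16 higher and 2 lower, adjusted p = 0.702) and smooth muscle markers (4 of 14 higher and 4 lower, adjusted p = 0.981) did not pass. Adipocyte markers (2 of 7 lower, adjusted p = 0.334), skeletal muscle markers (2 of 7 lower, adjusted p = 0.229) and epicardial markers (4 of 9 higher, adjusted p = 0.239) did not pass either. Adjusted over the list alone, the counts were 1 and 5 for contractile genes, 2 and 3 for immediate early genes, 2 and 2 for the clock, 5 and 5 for smooth muscle and 7 and 5 for fibroblast markers, and the same as over all genes for the other 11 lists. Among the erythroid genes Alas2 differed by log2 -1.87 and Hbb-b2 by log2 -0.80. Camera pointed down for immediate early genes, whose median and mean were above 0, and for smooth muscle markers, whose mean was.

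Most genes that changed after TAC in one genotype changed the same way in the other. Of 4205 genes changed in both, 4203 moved the same way, 2294 higher (748 by chance) and 1909 lower (635 by chance). The TAC effects correlated with r = 0.891 across genes, which are not independent replicates. Both contrasts hold the same run difference, which can by itself give such agreement. The chance counts take the contrasts as independent and leave that out. The difference between the KO effect after TAC and the KO effect in basal hearts, in which a shift shared by a whole run cancels, was tested directly. This test found 0 genes in limma (952 at an unadjusted p under 0.05, where 613 are expected; smallest adjusted p = 0.464), and 166 with array weights (52 higher and 114 lower). The 5 genes with the smallest p, none of which passed, were Nlk (log2 -0.91), Mtx3 (log2 -0.97), Tmem37 (log2 1.16), Dmxl1 (log2 -0.80) and Tm2d1 (log2 -0.57). Nppb, at 12.32 ± 0.12 in basal wild type and 12.93 ± 0.15 in basal knockout (n = 3 each) and 14.17 in both TAC groups, had a difference of log2 -0.61 (adjusted p = 0.499). Without TAC WT 4, 8 genes passed with a lower KO effect after TAC, among them Cxcl9 (log2 -2.86), Gbp3 (log2 -2.50), Gbp2 (log2 -2.45) and the peptide transporter Tap1 (log2 -1.42). Without TAC WT 1, Pam passed (log2 1.73, adjusted p = 0.0456). Cxcl9, Tap1 and Pam were chosen after their values were seen.

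**Figure D2:**
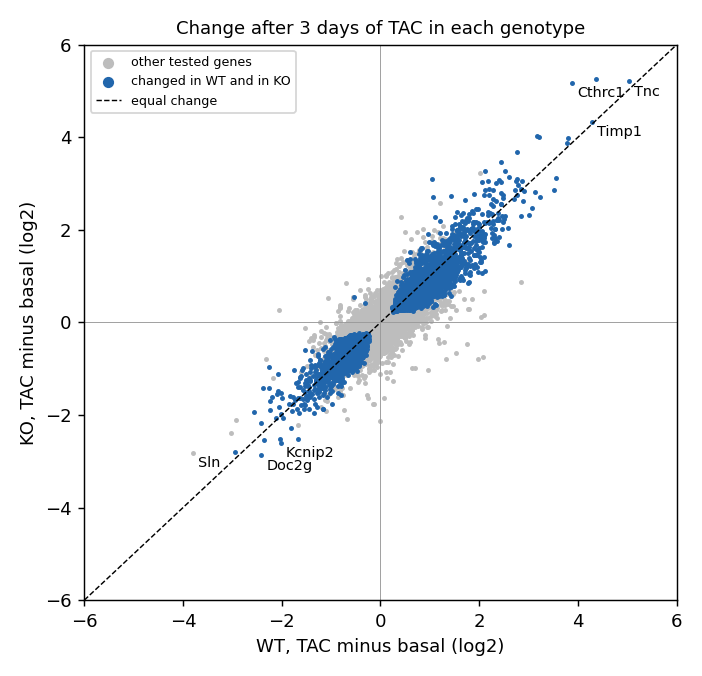
Log2 change after TAC in wild type (x axis) and in knockout (y axis) for the 12260 genes tested, with 1 point per gene. Blue points passed in both genotypes, and the dashed line marks an equal change; 4203 of the 4205 blue points moved the same way.

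There were 4 lists whose KO effect differed between TAC and basal hearts. Interferon response genes had a KO effect that was lower after TAC (median log2 -1.02, 17 of 18 members below 0, adjusted p = 3.99e-09, and adjusted p = 0.763 with an estimated correlation), led by the guanylate-binding proteins Gbp2 and Gbp3 (both log2 -1.92), and 7 members passed when adjusted over the list alone. Chaperones did too (median log2 -0.35, 24 of 26 members below 0, adjusted p = 3.29e-06, 0.763 with an estimated correlation), with Hsph1 at log2 -1.63, and 2 passed when adjusted over the list alone. Ribosomal proteins had a higher KO effect after TAC (median log2 0.15, 36 of 39 members above 0, adjusted p = 3.76e-05, 0.819 with an estimated correlation). Its mean, log2 0.15, was 0.06 without TAC WT 1, 0.24 without TAC WT 3, 0.10 without TAC KO 4 and 0.10 after median centring. Mitochondrial regulators had a lower one (median log2 -0.20, 19 of 22 members below 0, adjusted p = 0.0247, 0.819 with an estimated correlation). That call was lost without basal WT 3, basal KO 2, TAC WT 1, TAC WT 2 or TAC KO 4 (adjusted p = 0.0501 to 0.208), after quantile normalization (adjusted p = 0.0902) and with the mean of probe sets (adjusted p = 0.0615), and the mean of log2 -0.20 was -0.10 without TAC WT 1, -0.13 after quantile normalization and -0.33 without TAC WT 3. The other 24 lists did not pass (adjusted p = 0.0632 to 0.686), and for fatty acid oxidation and immediate early genes the median and mean were below 0 where camera pointed up. The number of lists was 9 without basal WT 1, 7 without TAC WT 1, 12 without TAC WT 3, 8 without TAC WT 4 and 10 without TAC KO 2.

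The next comparison asks how the loss of Hspb8 changed the ventricle after 3 days of TAC. Fbln5, a secreted protein that assembles elastic fibres, was higher in knockout, at 9.56 ± 0.12 (n = 4) against 8.60 ± 0.06 (n = 4) in wild type (1.94-fold, log2 0.96, SE 0.12, adjusted p = 0.0163), with no overlap between the groups. Basal hearts read 9.05 ± 0.24 in knockout and 8.89 ± 0.21 in wild type. Fbln5 was the 1 gene of 12260 that passed in limma, where 998 had an unadjusted p under 0.05 and 613 are expected, and 489 genes did not overlap (3.99%, against 2.86% by chance). With array weights 2880 genes passed (1256 higher and 1624 lower); TAC KO 3 (4.73) and TAC WT 2 (3.52) each weighed more than the other 3 arrays of their group together, and TAC WT 3 had a weight of 0.187. Other elastic fibre and matrix genes had higher values in knockout that did not pass: elastin, Eln (2.00-fold, adjusted p = 0.1), Mfap4 (log2 1.02, adjusted p = 0.106) and Col18a1 (log2 0.75, adjusted p = 0.29). Tested as single probe sets, 7 passed: a pair for Hspb8, 1 each for Fbln5, Ptn, Thbs2 and Ctse, and 1 without a gene name. Ptn, the growth factor pleiotrophin, was higher by 1 of its probe sets (log2 1.81, SE 0.22, adjusted p = 0.00861). Another probe set stood for Ptn in the tests per gene, where it did not pass. The thrombospondin Thbs2 (log2 0.88, adjusted p = 0.029) and the protease Ctse (log2 0.81, adjusted p = 0.0327) were higher by a probe set as well. Ptn, Thbs2 and Ctse fall outside the naming rule and were chosen after their values were seen. The call of Fbln5 was lost without TAC WT 2 (adjusted p = 0.0737), TAC KO 1 (0.0659), TAC KO 2 (0.0591) or TAC KO 3 (0.0546) and with the replicate block (0.0964); its adjusted p ran from 0.000802 to 0.0964 over 28 alternatives.

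Fibroblast markers were higher in TAC knockout than in TAC wild type. All 18 members had higher means (median log2 0.51), and the list passed by camera with the preset correlation (adjusted p = 2.3e-10), with an estimated correlation (adjusted p = 0.0301) and by fry (adjusted p = 0.0199). Its mean per array, relative to basal wild type, was 0.48 ± 0.15 in knockout and -0.01 ± 0.19 in wild type (n = 4 each, exact permutation p = 0.0286, 2-sided, the smallest that 4 against 4 arrays can give, and 0.4 adjusted over the lists). The transcription factor Tcf21 (log2 0.56), the proteoglycan Lum (log2 0.53), Islr (log2 0.93) and the receptor Pdgfra (log2 0.40) had higher values, and 6 members passed when adjusted over the list alone against 0 over all genes. Matrix genes had higher means for 35 of 37 members, with 0 past the threshold over all genes (median log2 0.49, adjusted p = 3.39e-15, and adjusted p = 0.419 with an estimated correlation), and 4 passed when adjusted over the list alone. The matrix list's mean difference was log2 0.55, and 0.32 without TAC WT 1. Macrophage markers had higher means for 22 of 23, again with 0 over all genes (median log2 0.46, adjusted p = 9.94e-07, 0.482 with an estimated correlation), 1 of which passed when adjusted over the list alone; the scavenger receptor Cd163 differed by log2 0.95 and Lgals3 by log2 0.85. Their mean difference of log2 0.44 was 0.22 without TAC WT 1 and 0.86 without TAC WT 3.

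Interferon response genes were lower in TAC knockout. All 18 members had lower means (median log2 -0.81, adjusted p = 1.73e-13, and adjusted p = 0.419 with an estimated correlation), 13 of them passing when adjusted over the list alone and 0 over all genes. Gbp3 was 3.05-fold lower (log2 -1.61, adjusted p = 0.307), Gbp2 2.92-fold lower (log2 -1.55, adjusted p = 0.306) and Oasl2 2.58-fold lower (log2 -1.37, adjusted p = 0.299). The list's mean per array was 1.26 ± 0.70 in TAC wild type, 0.44 ± 0.16 in TAC knockout (n = 4 each, exact permutation p = 0.143, 2-sided), 0.00 ± 0.22 in basal wild type and 0.19 ± 0.13 in basal knockout (n = 3 each). Of the TAC wild-type arrays, 1, 2 and 3 read 1.44, 1.66 and 1.71 and array 4 read 0.22, beside 0.30 to 0.67 in knockout.

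Leaving out single wild-type arrays changed how many genes passed after TAC. Without TAC WT 3, 107 genes passed, 88 higher and 19 lower in knockout, among them 8 of 23 macrophage markers and 6 of 37 matrix genes. That array had the highest macrophage mean of the TAC wild-type arrays (2.50, against 0.59 to 1.03). Ptn (log2 2.23), Sfrp2, a secreted Wnt inhibitor (log2 1.81), fibronectin, Fn1 (log2 1.55), the oxidase Nox4 (log2 1.42) and Apoe (log2 1.40) were higher there. Without TAC WT 4, 19 genes passed, 17 lower, of which 8 belong to the 18 interferon genes, with the chemokine Cxcl9 at log2 -2.75, Gbp3 at log2 -2.19 and Gbp2 at log2 -2.08. Array 4 had the lowest interferon mean of its group, so the arrays left out bear on these lists, and the counts of members are given without a test. The 2 higher genes were Eln (log2 1.09) and Fbln5 (log2 0.94). Without TAC WT 1, Fbln5 and Pam passed; without TAC KO 4, Fbln5, Gxylt2 and Tmem176a; without TAC WT 2, TAC KO 1, TAC KO 2 or TAC KO 3, 0 genes. These genes were chosen after their values were seen. On the first principal component of all arrays (69.5% of the variance), TAC wild-type arrays spread from -4.18 to 61.3, with array 3 the highest, and TAC knockout arrays from 17.4 to 49.6, while basal arrays lay between -43.9 and -35.7.

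**Figure D3:**
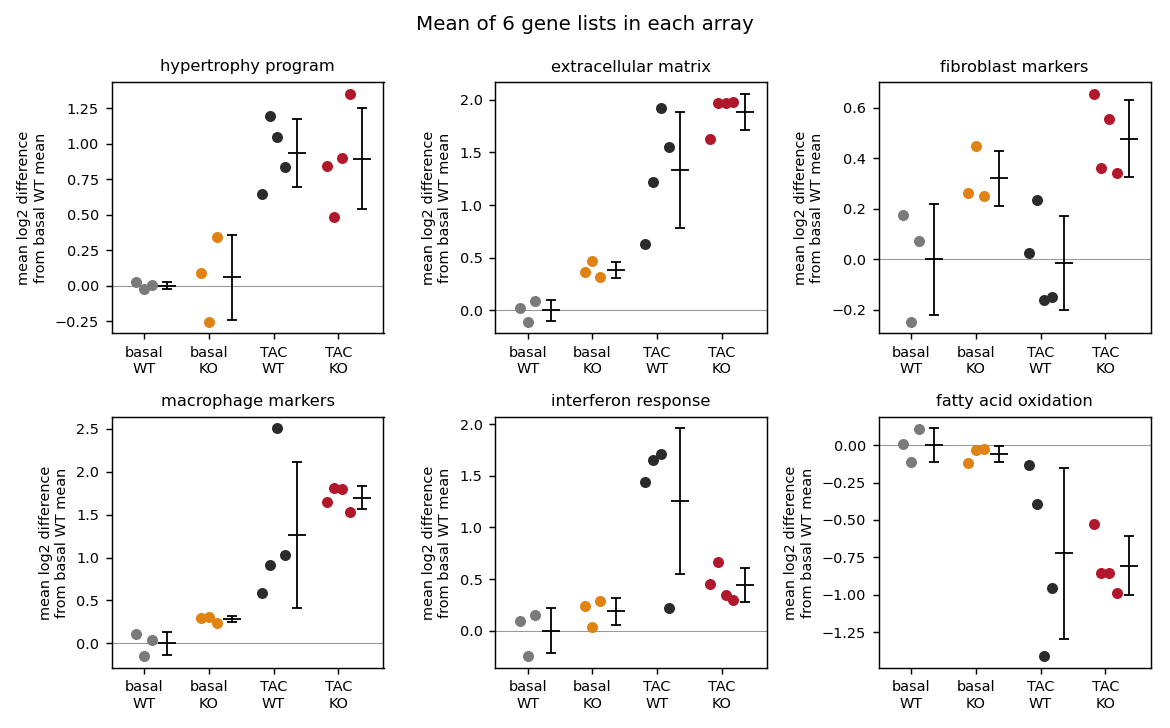
Mean log2 difference of 6 gene lists from their mean in basal wild type, with 1 point per array and bars for the group mean ± SD. After TAC the fibroblast list lies at 0.48 ± 0.15 in knockout and -0.01 ± 0.19 in wild type, and 1 of the 4 TAC wild-type arrays lies below the 4 TAC knockout arrays on the interferon list.

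A further 8 lists passed between TAC knockout and TAC wild type with the preset correlation, without a member past the threshold over all genes. Chaperones were lower in knockout (median log2 -0.15, 22 of 26 members below 0, adjusted p = 0.00238, and adjusted p = 0.431 with an estimated correlation), with Hsph1 at log2 -0.73; their mean went from log2 -0.22 to -0.13 without TAC WT 2. Mitochondrial regulators were lower (median log2 -0.22, 21 of 22 below 0, adjusted p = 6.36e-05, 0.431 with an estimated correlation; 2 passed when adjusted over the list alone), with the mitochondrial polymerase Polg at log2 -0.41. Their mean of log2 -0.21 was -0.10 without TAC WT 1 and -0.33 without TAC WT 3. Oxidative phosphorylation (median log2 -0.08, 65 of 74 below 0, adjusted p = 0.00961, 0.873 with an estimated correlation) and the TCA cycle (median log2 -0.11, 18 of 20 below 0, adjusted p = 0.0369, 0.783 with an estimated correlation) were lower. Ribosomal proteins (median log2 0.08, 35 of 39 above 0, adjusted p = 0.00133, 0.783 with an estimated correlation) and cell cycle genes (median log2 0.35, 27 of 35 above 0, adjusted p = 0.00189, 0.783 with an estimated correlation) were higher. Neutrophil markers (median log2 0.38, 5 of 5 above 0, adjusted p = 0.0337, 0.431 with an estimated correlation) and epicardial markers (median log2 0.43, 8 of 9 above 0, adjusted p = 0.00827, 0.431 with an estimated correlation) were higher as well.

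Of these 12 calls, 6 were kept with each of the 14 arrays left out in turn: fibroblast, matrix, macrophage, interferon, chaperone and mitochondrial regulator lists. Oxidative phosphorylation, the TCA cycle, cell cycle and ribosomal proteins lost theirs without TAC WT 1 (adjusted p = 0.668 to 0.839), without TAC WT 2 (0.137 to 0.849) and without TAC KO 4 (0.0528 to 0.961). Their means were log2 -0.09, -0.10, 0.32 and 0.08 with all arrays, -0.01, -0.01, -0.07 and -0.01 without TAC WT 1, -0.02, -0.03, 0.12 and 0.03 without TAC WT 2, -0.20, -0.25, 0.76 and 0.17 without TAC WT 3, and -0.03, -0.04, 0.23 and 0.03 without TAC KO 4. The mean of the TCA cycle was log2 -0.16 with the mean of probe sets. Without TAC KO 1 the first, the second and ribosomal proteins were at log2 -0.14, -0.17 and 0.13, and ribosomal proteins were at log2 0.13 without TAC WT 4 and 0.04 after median centring. Neutrophil markers lost their call without TAC WT 1, TAC WT 2, TAC KO 1 or TAC KO 4 (adjusted p = 0.0849 to 0.231), and their mean of log2 0.39 was 0.18 without TAC WT 1, 0.59 without TAC WT 3 and 0.24 with no filter. The call was also lost for epicardial markers without TAC WT 2 (0.0503) or TAC KO 4 (0.0528). After quantile normalization, neutrophil markers (0.0791), epicardial markers (0.0717) and the TCA cycle (0.0536) did not pass. In all, 6 lists passed without TAC WT 2 and 7 without TAC KO 4.

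The remaining lists did not pass after TAC between the genotypes with the preset correlation. Among them were the hypertrophy and fetal program (adjusted p = 0.977), contractile genes (0.364), the unfolded protein response (0.507), the proteasome (0.054), autophagy (0.77) and fatty acid oxidation (0.77). The adjusted p was also above 0.05 for glycolysis (0.184, with 1 member lower when adjusted over the list alone), STAT3 targets (0.427), immediate early genes (0.184), and the clock (0.77). The same held for markers of lymphocytes (0.0993), endothelium (0.0882, with 1 member higher and 1 lower when adjusted over the list alone), smooth muscle (0.128), adipocytes (0.155), skeletal muscle (0.337) and atrial cardiomyocytes (0.831). For the hypertrophy, autophagy and atrial lists the median and mean were below 0 and camera pointed up. Nppb (log2 0.00), Myh7 (log2 0.49) and Nppa (log2 0.10) had adjusted p of 0.995, 0.866 and 0.952 between TAC knockout and TAC wild type. Without TAC WT 3, Myh7 was at log2 -0.26 (adjusted p = 0.623).

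The last comparison asks what the loss of Hspb8 changed in the basal ventricle. No gene passed in limma on the probe set with the highest mean (0 of 12260; 707 at an unadjusted p under 0.05, where 613 are expected; smallest adjusted p = 0.208). Beside Hspb8, the genes with the smallest p were the mitochondrial nucleotide carrier Slc25a33 (log2 -1.13, adjusted p = 0.208), Adpgk (log2 -0.78), Trim65 (log2 0.69) and Tm7sf3 (log2 0.68), the last 3 with an adjusted p = 0.223. The groups did not overlap for 1666 genes (13.6%, against 10% by chance), and 3 against 3 arrays cannot give an exact permutation p under 0.1. The knockout effects in basal and TAC hearts were nearly unrelated across genes, which are not independent replicates (Pearson r = 0.00662, Spearman rho = -0.0533; r = -0.0655 without TAC WT 1 and 0.0822 without TAC WT 3). With 0 genes past the threshold here and 1 after TAC, noise in single genes can hide a shared effect. The low correlation therefore does not show that the effects differ.

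In basal hearts 7 lists passed with the preset correlation and none with an estimated one. No member of these lists passed over all genes, so the counts of members are of means above or below 0. Matrix genes had higher means in knockout for 35 of 37 members (median log2 0.34, adjusted p = 2.06e-06, and adjusted p = 0.852 with an estimated correlation), with Cilp at log2 1.38, Col3a1 at log2 1.02 and Mfap4 at log2 0.81. Fibroblast markers had higher means for 16 of 18 (median log2 0.24, adjusted p = 0.00373, 0.755 with an estimated correlation), with Col1a1 at log2 0.96. The 2 lists kept their calls with each array left out in turn, and the fibroblast mean went from log2 0.32 to 0.20 without basal WT 2. Chaperones had higher means for 24 of 26 (median log2 0.19, adjusted p = 0.00013, 0.755 with an estimated correlation), with the heat shock factors' targets Dnajb1 at log2 1.25 and Hsph1 at log2 0.90. Their mean of log2 0.34 was 0.53 without basal KO 2 and 0.19 without basal KO 3, where the call was lost (adjusted p = 0.084); that array was run on another day than the other basal arrays. Macrophage markers had higher means for 20 of 23 (median log2 0.29, adjusted p = 0.0457, 0.986 with an estimated correlation), a call lost without any 1 of the 6 basal arrays, TAC KO 1 or TAC KO 4 (adjusted p = 0.0521 to 0.243) and after median centring (adjusted p = 0.0614).

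The lists lower in basal knockout were STAT3 and acute phase targets, ribosomal proteins and atrial markers. STAT3 targets had a median of log2 -0.14 (adjusted p = 0.00373, and adjusted p = 0.852 with an estimated correlation), with the transcription factor Cebpd at log2 -1.35 and the metallothionein Mt2 at log2 -1.04. Their mean of log2 -0.23 was -0.42 without basal WT 1 and -0.07 without basal WT 2, where the call was lost (adjusted p = 0.561). Ribosomal proteins had lower means for 31 of 39 members (median log2 -0.07, adjusted p = 0.0071, 0.986 with an estimated correlation), a call lost without basal KO 3 (adjusted p = 0.084), with no filter (0.0734) and after quantile normalization (0.139). Atrial markers had lower means for 9 of 9 (median log2 -0.55, adjusted p = 0.00373, 0.852 with an estimated correlation), with Sln at log2 -1.71 and Mybphl at log2 -1.13. Their mean per array spread from -2.14 to 0.57 in basal knockout against -0.18 to 0.11 in basal wild type, and the mean difference of log2 -0.80 was -0.13 without basal KO 2 (adjusted p = 0.447) and -1.49 without basal KO 3. Adjusted over the list alone, 2 genes of the hypertrophy list were higher and 1 each of the STAT3, atrial and epicardial lists were lower, against 0 over all genes.

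The other 21 lists did not pass in basal hearts, where the hypertrophy list had an adjusted p = 0.0698, with Nppb at log2 0.61 and skeletal actin, Acta1, at log2 1.33, and oxidative phosphorylation 0.0842. The adjusted p was 0.109 for the unfolded protein response and for immediate early genes, 0.206 for interferon response, 0.26 for the clock, 0.33 for lymphocyte markers and 0.481 for fatty acid oxidation, the TCA cycle and neutrophil markers. It was 0.484 for glycolysis and adipocyte markers, 0.563 for autophagy, 0.669 for the proteasome, and 0.955 for contractile genes, cell cycle genes, mitochondrial regulators and markers of endothelium, smooth muscle, skeletal muscle and epicardium. Cell cycle genes, endothelial and skeletal muscle markers had a median and mean above 0 where camera pointed down, and the median of contractile genes was 0.

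Genes tied to the signalling of Hsp22 were followed in every comparison. Stat3 was 1.54-fold higher after TAC in wild type (log2 0.62, adjusted p = 0.00191) and log2 0.45 higher in knockout (adjusted p = 0.0134). Its 4 probe sets differ in sign, and their mean gave log2 0.20 (adjusted p = 0.171) and log2 0.13 (adjusted p = 0.391). Between genotypes Stat3 differed by log2 0.17 in basal hearts and log2 0.00 after TAC (adjusted p = 0.999 and 0.995). Nos3, the endothelial nitric oxide synthase, fell after TAC in wild type (log2 -0.78, adjusted p = 0.000303) and knockout (log2 -0.60, adjusted p = 0.00176). Nos2, the inducible synthase, lay below the filter, at 5.21 ± 0.36 in basal wild type, 5.18 ± 0.25 in basal knockout (n = 3 each), 4.61 ± 0.09 in TAC wild type and 4.90 ± 0.11 in TAC knockout (n = 4 each), so no difference is given for it. Bag3, the co-chaperone that pairs with Hsp22, differed by log2 -0.15 after TAC in wild type, -0.30 in knockout, 0.06 between genotypes in basal hearts and -0.09 after TAC, none of which passed (adjusted p = 0.422, 0.121, 0.999 and 0.909).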

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

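The tests of explanations and the counts over other splits in this part were chosen after the results they concern were seen.

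Interferon response genes had a lower KO effect after TAC than in basal hearts, a difference between groups in the list test (median log2 -1.02; adjusted p = 0.763 with an estimated correlation), and all 18 had lower means in TAC knockout than in TAC wild type. A single aberrant array as the whole source is argued against: the mean difference of log2 -0.814 kept at least log2 -0.662 with any 1 of the 8 TAC arrays left out, the smallest being without TAC WT 3, and was log2 -1.16 without TAC WT 4, whose list mean of 0.215 lay below those of the 4 knockout arrays. Fewer macrophages as the whole source are argued against only in part, since their markers would have to fall as far. Macrophage minus interferon mean per array was 1.26 ± 0.13 in knockout and 0.00 ± 0.93 in wild type (n = 4 each, exact permutation p = 0.0286). The interferon list was taken up because it was lower in these same arrays, so part of this difference is built in. The macrophage markers alone were 0.440 higher on the log2 scale (SE 0.431, exact permutation p = 0.371), or 0.217 without TAC WT 1 and 0.855 without TAC WT 3. A rise of macrophages is thus not shown, and some fall is not excluded. What stays open is chance, with an exact permutation p = 0.143 for the list mean between TAC genotypes and an adjusted p = 0.419 with an estimated correlation. A response to TAC that differs with Hspb8 stays open too. The difference of KO effects tests for it, and camera called the list at the preset correlation but not with an estimated one (adjusted p = 0.763), which leaves it undecided.

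Matrix genes were higher in TAC knockout, by log2 0.553 (SE 0.288) in the list mean (exact permutation p = 0.0571), or 0.319 without TAC WT 1. A smaller share of cardiomyocyte RNA would raise the markers of all other cell types alike. Endothelial markers were not higher in knockout (log2 -0.08, exact permutation p = 0.314). Other markers went the way a smaller share would give, each with an exact permutation p of 0.0571 or more. List means were higher for macrophage (log2 0.44), neutrophil (0.39), adipocyte (0.36), epicardial (0.35), smooth muscle (0.13) and lymphocyte markers (0.09). Contractile genes were lower (log2 -0.12). The fibroblast minus endothelial mean per array was 0.76 ± 0.09 in knockout and 0.19 ± 0.09 in wild type (n = 4 each, exact permutation p = 0.0286, the smallest possible). This argues against that share as the whole cause only in part. The endothelial list stands against the other marker lists named, and 5 of the 18 fibroblast markers are matrix genes themselves. For the extent of the surgery response, the first principal component of the TAC arrays was taken as a covariate, which moved the cell cycle median from log2 0.35 to 0.13. With it the matrix difference was log2 0.432 (SE 0.105) and the list passed (camera adjusted p = 7.32e-13, and 0.228 with an estimated correlation). This argues against that extent as the whole cause only as far as the component measures it. The component comes from the same arrays, matrix genes included, and may hold the extent only in part. What stays open is chance, that extent or a smaller cardiomyocyte share as a part of the cause, and more fibroblast RNA in knockout. The 13 fibroblast markers outside the matrix list were 0.427 higher on the log2 scale (13 of 13 above 0, exact permutation p = 0.143). More fibroblast RNA and an effect of Hspb8 on matrix genes, which may hold beside it, cannot be told apart with 4 arrays per group.

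Many genes changed between basal and TAC arrays, which were hybridized in different runs. Among 9 hybridization controls added to every array, which stand outside the comparisons, CreX-3 was 0.418 and CreX-5 0.436 higher in the TAC run on the log2 scale, with no overlap between 6 and 8 arrays (exact permutation p = 0.000333, the smallest these arrays can give). Over the 9 controls the difference ran from log2 -0.11 to 0.44, with a median of 0.101 and 7 higher. The 12 probe sets for bacterial poly-A controls had lower means in the TAC run, with no overlap for PheX-3 (log2 -0.782), DapX-M (log2 -0.297) and PheX-M (log2 -0.172). The run and the surgery cannot be told apart, because no run holds arrays of each kind.

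Other lists with a KO effect that differed between TAC and basal hearts were chaperones (median log2 -0.35), mitochondrial regulators (median log2 -0.20) and ribosomal proteins (median log2 0.15), with adjusted p = 0.763, 0.819 and 0.819 with an estimated correlation. A probe set without a gene name, which the tests per gene do not use, was higher in TAC knockout (log2 1.23, adjusted p = 0.0451 over all probe sets), and no biological explanation was tested.

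Single arrays lay far from the others of their group for 5 genes and 2 list means: Myh7 in TAC WT 3 (10.24, against 13.19 to 13.28 in the other 3), Trim65 in TAC WT 4 (5.46), Bcat2 in TAC WT 3 (9.26), Dmxl1 in TAC WT 2 (8.77), Ces1d in TAC KO 1 (8.68), the matrix list in TAC KO 1 (1.63) and the epicardial list in TAC KO 2 (0.17). These are 7 of 164 groups of values tested (4.27%), where chance gives about 5%.

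Other splits of the same arrays into groups of the same sizes were fitted like the real ones. For the genes changed after TAC the real split gave the highest count in wild type (6214, against at most 5498 in other splits, with 1 of 35 splits giving as many). The same held in knockout (5451, against at most 2805, 1 of 35). This argues against chance but cannot exclude it, because 1 of 35 is the smallest share these splits can give. The real split also parts the 2 runs. Chance cannot be excluded for the genes between TAC knockout and TAC wild type, where 8 of 35 splits gave at least the real count of 1. The highest other split gave 1382 genes, far more than the real count, which points to a structure of the TAC arrays that does not follow genotype. For the difference of KO effects the real count was 0, so that each of 100 splits gave as many (100 of 100, highest other 2) and the count tests nothing. For lists, chance cannot be excluded after TAC between genotypes (12, highest other 17, 21 of 35 splits) or for the difference of KO effects (4, highest other 17, 94 of 100). Between TAC and basal the counts were 13 in wild type (highest other 17, 15 of 35) and 12 in knockout (highest other 14, 18 of 35). They cannot decide about chance, because other splits hold the surgery and run difference too, and a count leaves out which lists passed. The wild-type split of the 3 basal arrays and TAC WT 1 against the other TAC arrays gave 5498 genes and 14 lists. In basal hearts the 10 splits are too few: the real counts were 0 genes and 7 lists, the highest others 1 and 5, and 10 and 1 of the splits gave as many, where a count of 0 genes again tests nothing.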

How the results depend on the processing

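The settings that leave out probe sets able to bind other transcripts, use the first principal component of the TAC arrays as a covariate, permute list means, or scale the arrays before the list tests were chosen after seeing the data; the others were planned. For the 12 results that answer a comparison, 227 of 277 alternative values were the same and 50 moved. A count was the same if within 1.5 times or 0 in both, and the correlation if within the SD of its values with each array left out. Of 17498 values for named genes 17177 were the same, 185 weaker, 134 stronger and 2 reversed. Of 3052 values for lists 2774 were the same, 175 weaker and 103 stronger. For genes and lists a value was the same if it kept its side of the threshold. A change of sign where the value did not pass counted as the same. No gene passed between genotypes in basal hearts or for the difference of KO effects, so these labels had little room to change there. Between genotypes in basal hearts 1 gene passed with the mean of probe sets, 2 probe sets with every probe set tested, 5 genes with array weights (Hspb8, Lrp11, Slc25a33, Tm7sf3 and Trim65) and 1 without the probe sets able to bind other transcripts, against 0; the count of 1 is Hspb8 each time, and the 2 are its probe sets. Lrp11, Ptn, Eln and Gxylt2 were named after their values were seen. Between genotypes after TAC the counts were 5 (Fbln5, Hspb8, Ptn, Eln and Gxylt2), 7, 2880 (1256 higher and 1624 lower) and 2 (Fbln5 and Hspb8), 3 with quantile normalization (Fbln5, Ptn and Eln) and 0 with the replicate block, against 1. With array weights, which weighed TAC KO 3 at 4.73, TAC WT 2 at 3.52 and TAC WT 3 at 0.187, 166 genes had a KO effect that differed (52 higher, 114 lower). The replicate block rests on numbers that nothing in the labels says pair the arrays. Of 19 pairs of the same number 2 had r over 0.1 (range -0.161 to 0.594), TAC WT 1 with TAC KO 1 (0.594) and TAC WT 4 with TAC KO 4 (0.489). Pairs of other numbers ran from -0.579 to 0.577, so pairing is neither shown nor excluded. With the block Fbln5 had an adjusted p = 0.0964, within a range of 0.000802 to 0.0964. Between TAC and basal arrays in wild type 4126 genes passed with the stricter filter and 3521 with a fold change of at least 1.5, both of which keep fewer genes by construction, as do the 3090 in knockout with that fold change; every probe set tested gave 12300 and 10593, more because probe sets outnumber genes. With an estimated correlation 0, 1, 0, 0 and 0 lists passed (basal KO/WT, TAC KO/WT, TAC/basal in wild type and knockout, difference), with fry 0, 1, 11, 10 and 0, with exact permutation of list means 0 in each of 4 comparisons, with the covariate 7 lists after TAC between genotypes, and with median centring 10 lists for the difference (7 up, 3 down). The permutation could pass no list in basal hearts, where its smallest p is 0.1. Elsewhere its smallest p of 0.0286 leaves little room after adjusting over 28 lists, so these counts of 0 say little. Quantile normalization moved the median of all genes between TAC and basal wild type from log2 0.02 to -0.10 and median centring to 0.10; no called list changed the sign of its mean under either, and the uncalled glycolysis, smooth muscle and fibroblast lists did in wild type. The correlation of KO effects was 0.0444 with the mean of probe sets. Egr3 in wild type after TAC reversed with the mean of probe sets (log2 0.90, adjusted p = 0.0419, against -0.42), and Sox17 in knockout after TAC without the probe sets able to bind other transcripts (log2 -0.55, adjusted p = 0.0781, against 1.09). With each array left out in turn, genes between genotypes ran 0 to 0 in basal hearts and 0 (without TAC WT 2) to 107 (without TAC WT 3) after TAC, TAC against basal 4808 to 6842 in wild type and 4091 to 6133 in knockout, and the difference 0 to 8. Lists ran 5 to 9, 6 to 15, 11 to 14, 12 to 14 and 3 to 12, genes moving the same way 3362 to 4717, and the correlation of KO effects -0.0655 to 0.0822. Except where a setting's construction is named, the cause was not tested. Probe sets below the table median of 5.75 were not tested per gene, which is what signal over background limits here.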

Other observations

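The average of the KO effects in basal and TAC hearts was tested after seeing the data, as was the search near Hspb8. Averaged over both conditions, Ptn was higher in knockout by 1 of its probe sets (log2 1.22, adjusted p = 0.0278 over all probe sets). Mfap4, a microfibril protein of elastic fibres, was higher too (log2 0.92, adjusted p = 0.0453). The 3 probe sets of Hspb8 and 1 without a gene name (log2 -0.89, adjusted p = 0.0101) made up the rest of the 6 probe sets that passed. Tested per gene, 0 genes passed in limma (675 at an unadjusted p under 0.05), with Mfap4 at an adjusted p = 0.0747 and Fbln5 (log2 0.56) at 0.09. Ptn, Mfap4 and Fbln5 were named here after their values were seen.

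A knockout bred onto another strain can carry variants around the targeted gene. Within 20 Mb of Hspb8, 5 of 312 genes had a p under 0.01 for the average KO effect (1.60%), against 184 of 11904 elsewhere (1.55%; Fisher's exact test, p = 0.816, odds ratio 0.33 to 2.49). The interval leaves such variants open as a possible explanation for single genes near Hspb8.

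With the first principal component of the TAC arrays as a covariate, chosen after seeing the data, 7 lists passed between TAC knockout and TAC wild type with the preset correlation: fibroblast (median log2 0.57, adjusted p = 3.82e-13), matrix (0.40, 7.32e-13), interferon (-0.79, 2.62e-07), macrophage (0.30, 0.000446), chaperones (-0.20, 0.000597), mitochondrial regulators (-0.11, 0.00213) and epicardium (0.35, 0.026). With an estimated correlation none passed with the covariate (adjusted p = 0.167, 0.228, 0.648, 0.717, 0.615, 0.167 and 0.624 in that order).

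The 3' minus 5' difference of the actin control probe sets, a measure of RNA length, was log2 0.26 in basal wild type, 0.28 in basal knockout, 0.36 in TAC wild type and 0.35 in TAC knockout. It was larger in the TAC run than in the basal run (exact permutation p = 0.012), while that of Gapdh was smaller (-0.04 and 0.00 in basal wild type and knockout, -0.06 and -0.07 after TAC; exact permutation p = 0.0117) and that of the transferrin receptor ran from 1.33 to 1.70 over the groups (exact permutation p = 0.374). For actin it differed between TAC knockout and TAC wild type with an exact permutation p = 0.714.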
